A study of Arabidopsis thaliana with 18 samples.

How the data were processed

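RNA sequencing by Lasy-Seq version 1.1, a multiplexed protocol that reads transcripts from their 3′ ends, was made from Arabidopsis thaliana Col-0 seedlings, 18 libraries in 6 groups of 3. The groups, per the labels, were DMSO, coronatine and DPAM-1, each without and with 100 mM NaCl. Per the submitters' processing notes, the reads were handled with bcl2fastq, Trimmomatic, HISAT2, featureCounts and DESeq2 against the TAIR10 build; the notes give no versions and do not say what each did. The authors deposited a table of raw values in the unit count (reads per gene), and a second deposited table in the unit signal, whose values equal the counts divided by 1 factor per library. The count table was used for every result here, and the second table only for that check. All 14229 genes had at least 30 reads in each library, a minimum read off the values. Genes of low or no expression in any library are therefore outside every statement, also those that a treatment raised strongly.

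Gene codes were named from the TAIR10.1 annotation, which held 14105 of the 14229 codes, 6686 of them with a symbol. It was used for names only, and since it differs from the authors' build no coordinates are given. Gene length and GC content were not used. Reads of near-identical copies (GSTF6 and GSTF7, KIN1 and KIN2, VSP1 and VSP2, AOC1, AOC2 and AOC3, LHCB2.1 and LHCB2.2) cannot be assigned to 1 copy with certainty. Of the genes, 61 were encoded in the chloroplast and 2 in the mitochondrion, and they were kept.

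Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The edgeR expression filter removed 0 genes. Library totals were scaled by TMM factors, which lay between 0.847 and 1.13, and 1 quasi-likelihood model with a mean for each of the 6 groups was fitted to all 18 libraries. The biological coefficient of variation was 10.4%. Each gene was tested in 11 comparisons: DPAM-1 and coronatine against DMSO and against each other, without and under NaCl, NaCl against no NaCl in each compound, and the interactions of DPAM-1 and of coronatine with NaCl. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14229 genes of a comparison, and all tests were two-sided. Library totals lay between 13638981 and 37279056 reads, and without molecular identifiers the reads are not independent molecules.

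Lists of genes were fixed with the comparisons, the settings and most alternatives before the data were examined: 27 lists with 409 members, of which 2 were dropped because the annotation gives their codes other names, and 268 of 404 distinct genes were in the table. They cover brassinosteroid-induced, brassinosteroid biosynthesis and brassinosteroid signalling genes; JAZ repressor, jasmonate biosynthesis and catabolism, and jasmonate output genes; glucosinolate, flavonoid and anthocyanin, abscisic acid and osmotic stress, early stress transcription factor, sodium and potassium transport, auxin, ethylene, gibberellin, salicylic acid defence, xenobiotic detoxification, iron deficiency, heat shock, hypoxia, cell division, circadian clock, photosynthesis, root hair, endodermis, guard cell, touch, and seed storage and maturation genes. Lists were known from general plant biology and not taken from these libraries. XTH22 is in the brassinosteroid-induced and touch lists, GASA6 in the brassinosteroid-induced and gibberellin lists, and IAA1 and IAA19 in the brassinosteroid-induced and auxin lists. ERF1, not analysed here, is in the jasmonate output and ethylene lists. The 26 lists with at least 3 members in the table were tested with camera (preset correlation 0.01), with an estimated correlation beside it (its Benjamini-Hochberg adjusted p is called the estimated-correlation p), and with fry, which asks whether the members move one way on balance or change in either direction. Members were also counted adjusted over the list alone.

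Genes were named by a rule. In each comparison these were the 6 highest and 6 lowest called genes with a mean log2 CPM of at least 2 and, outside the interactions, groups that do not overlap. From each list with a called member they were up to 4 members of smallest p in its main direction and 1 in the other, and 11 marker genes were named whatever their p, 8 of which were present (CYP734A1, SAUR15 and RD29B were not).

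The alternatives fixed in advance were a log2 fold change of at least 1 besides the adjusted p, DESeq2 1.42.0 (Wald test), RLE and upper-quartile factors, no filter, at least 10 reads in 9 libraries, organelle genes removed, the replicate number as a block, only the groups compared, an estimated correlation in camera, and each library left out in turn. Added after the data had been seen were a mean count of at least 100, library totals without TMM, the DMSO and coronatine libraries numbered 3 both left out, and, for coronatine against DMSO, the 2 groups alone with the block. The labels do not say that equal replicate numbers belong together. Same-numbered DMSO and coronatine libraries nevertheless deviated from their group means together (correlations across genes of 0.13, 0.30 and 0.50), which is why the blocked counts are given for that comparison. DMSO replicate 1 with coronatine replicate 2, and DMSO replicate 2 with coronatine replicate 1, also correlated (0.18 each). Libraries numbered 1 and 2 are thus not shown to pair by number, and those numbered 3 stood out.

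The model was tested on simulated data with known changes: for DPAM-1 against DMSO it recovered 65.7% of 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes, with 6 false calls among 177. For the DPAM-1 interaction these were 28.4%, 77.6% and 100%, with 5 false among 142. Comparisons against the same DMSO libraries share their errors, so the overlap of DPAM-1 and coronatine was also computed in 20 simulations of unchanged groups. For each comparison the libraries were also regrouped, in all 10 ways for 3 against 3 and in 40 drawn ways for an interaction.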

Results

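Transcripts were counted in Arabidopsis thaliana Col-0 seedlings kept in liquid medium with 1% DMSO as solvent control, with 5 µM coronatine, or with 5 µM DPAM-1. The treatment labels of the compound groups name no solvent, so a difference in solvent cannot be told apart from a compound effect against DMSO. Coronatine is a bacterial toxin that mimics jasmonoyl-isoleucine, the active form of the hormone jasmonate, and DPAM-1 is a compound the labels give only by its code name. The compounds were added 4 days after germination, 100 mM NaCl followed 16 h later in 3 of the 6 groups, and seedlings were harvested 2 h after that. The treatment labels of the groups without NaCl name neither a mock addition nor a harvest time. Effects of the addition itself or of time therefore cannot be told apart from those of NaCl in any comparison of NaCl with no NaCl. Each of the 6 groups had 3 libraries, 18 in all. The labels number these libraries and do not say whether they came from separate cultures, so they may be technical replicates.

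The deposited table held 14229 genes, each with at least 30 reads in every library. None of the 11 fixed seed storage and maturation genes was among them, so that list was not tested. Other lists lost members too. The table held 6 of 16 early stress, 20 of 32 abscisic acid, 8 of 22 auxin and 4 of 16 salicylic acid defence genes. List counts below cover only the members measured. Total counts were 18556737, 19908297 and 17266389 reads in the DMSO libraries and 34202322, 19637279 and 24485460 in DMSO with NaCl. Coronatine libraries held 31460853, 22493442 and 15011305 reads without NaCl and 37279056, 17891336 and 22993345 with it. The DPAM-1 libraries held 13638981, 18797749 and 25194993 reads, and those of DPAM-1 with NaCl 21736675, 13691358 and 14833000. Throughout, a log2 fold change is followed by its standard error (SE, from 3 libraries per group) and levels are reads scaled to library size (CPM) with their standard deviation (SD).

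**Figure D1:**
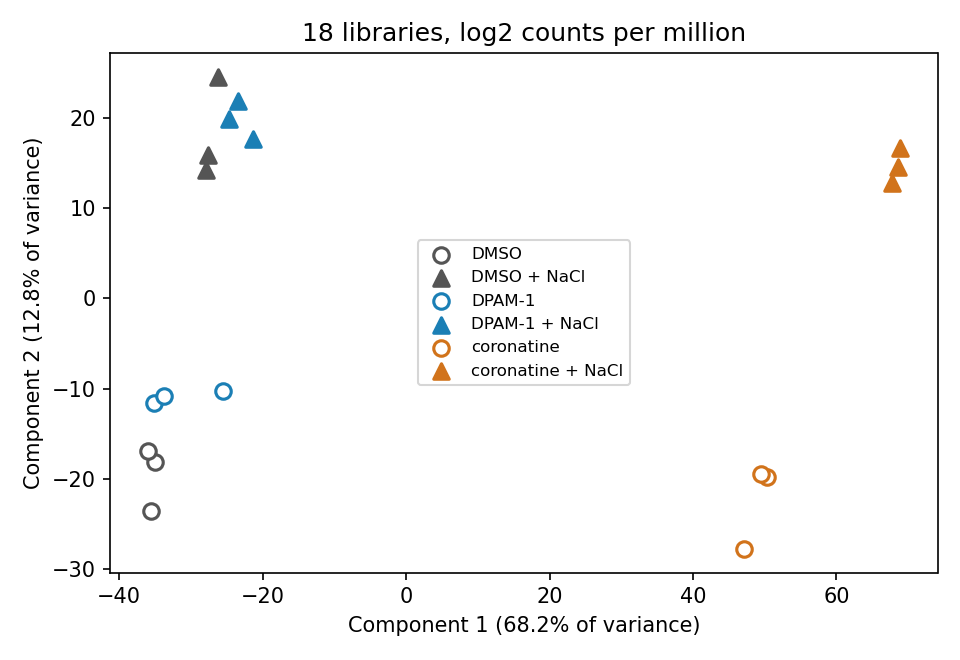
Principal components of the 18 libraries from log2 CPM, first component (68.2% of the variance) on the horizontal axis and second (12.8%) on the vertical axis, each point a library, coloured by compound and shaped by NaCl. Coronatine libraries lie apart from the others along the first component, and libraries with and without NaCl lie apart along the second.

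The first comparison asked what DPAM-1 does without salt. Stress regulators were higher after DPAM-1 than in DMSO. The genes ZAT10 (AT1G27730) and ZAT12 (AT5G59820), zinc-finger transcription factors of abiotic stress responses, stood 2.46-fold and 2.50-fold higher. WRKY33 (AT2G38470), a defence transcription factor, was 2.32-fold higher. ZAT10 rose from 5.81 CPM ± 1.76 (SD, n = 3) to 14.4 CPM ± 1.94 (SD, n = 3). TCH3 (AT2G41100), a calmodulin-like gene that responds to touch, rose 3.53-fold to 111 CPM ± 5.99 (SD, n = 3). XTH22 (AT5G57560), a xyloglucan-modifying cell wall enzyme also known as a touch gene, rose 2.71-fold to 43.1 CPM ± 1.28 (SD, n = 3). The largest rise among the named genes was that of AT2G44130, from 3.67 CPM ± 0.619 (SD, n = 3) to 16.1 CPM ± 1.16 (SD, n = 3), a log2 fold change of 2.13 ± 0.14, adjusted p = 7.7e-09. Genes of detoxification rose as well, among them the glutathione transferases GSTF6 (AT1G02930) at 0.77 ± 0.09, adjusted p = 3.3e-05 and GSTF7 (AT1G02920) at 0.96 ± 0.12, adjusted p = 1.4e-04. The reductase OPR1 (AT1G76680) was at 0.62 ± 0.11, adjusted p = 0.00419. GSTF6 and GSTF7 are near-identical in sequence, so the reads given to each are uncertain.

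By the lists, 4 of 6 early stress transcription factor genes rose (6 adjusted over the list alone), with a median log2 fold change of 1.06 and camera adjusted p = 2.8e-08, estimated-correlation p = 0.00629. Of the 5 touch genes 2 rose, TCH3 at 1.82 ± 0.19, adjusted p = 5.7e-06 and XTH22 at 1.44 ± 0.28, adjusted p = 0.00791 (3 adjusted over the list alone), camera adjusted p = 1.2e-05, estimated-correlation p = 0.0141. Among 20 xenobiotic detoxification genes 4 rose and none fell (11 adjusted over the list alone), camera adjusted p = 3.7e-09, estimated-correlation p = 0.0252. Of 8 root hair genes 1 fell, PRP3 (AT3G62680), a cell wall protein gene, at -0.48 ± 0.10, adjusted p = 0.0133 (2 lower over the list alone, camera adjusted p = 0.288, estimated-correlation p = 0.483), a call that ended without DMSO replicate 2 or DPAM-1 replicate 2 or 3 (up to 0.0836). Of the 18 brassinosteroid-induced genes measured, 3 rose, 1 fell and 14 did not pass (5 higher and 5 lower adjusted over the list alone). The median of the list was 0.05 with camera adjusted p = 0.796, estimated-correlation p = 0.858. Fry's test for change in either direction gave an adjusted p of 1.1e-06. That test does not ask whether the list changed more than other genes, of which many did: 2021 of 14229 genes had an unadjusted p under 0.05. The 3 that rose, XTH22, XTH23 (AT4G25810) at 1.32 ± 0.29, adjusted p = 0.0211 and XTH24 (AT4G30270) at 0.84 ± 0.19, adjusted p = 0.0341, all encode wall enzymes of 1 family. EXPA1 (AT1G69530), an expansin that loosens walls, fell 1.48-fold from 82.5 CPM ± 5.68 (SD, n = 3) to 55.9 CPM ± 3.44 (SD, n = 3). None of the 7 brassinosteroid biosynthesis genes passed the edgeR test (0 called, 2 at an unadjusted p under 0.05, 0 by DESeq2). CPD (AT5G05690), a P450 enzyme of the pathway whose gene the hormone represses, was at -0.09 ± 0.10 (95% interval -0.30 to 0.13), and DWF4 (AT3G50660), another, at -0.35 ± 0.16 (-0.69 to -0.02). For that list the median was 0.12 and the mean -0.02, opposite in sign (camera adjusted p = 0.589, estimated-correlation p = 0.622). No brassinosteroid signalling gene of 10 passed either (0 called, 1 unadjusted, 0 by DESeq2). The median was 0.03, turned below 0 with library totals, the mean -0.01 and camera adjusted p = 0.725, estimated-correlation p = 0.719. The auxin- and brassinosteroid-responsive gene IAA19 (AT3G15540) was at 0.10 ± 0.20 (95% interval -0.31 to 0.52), so a change of 2-fold is outside its interval.

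**Figure D2:**
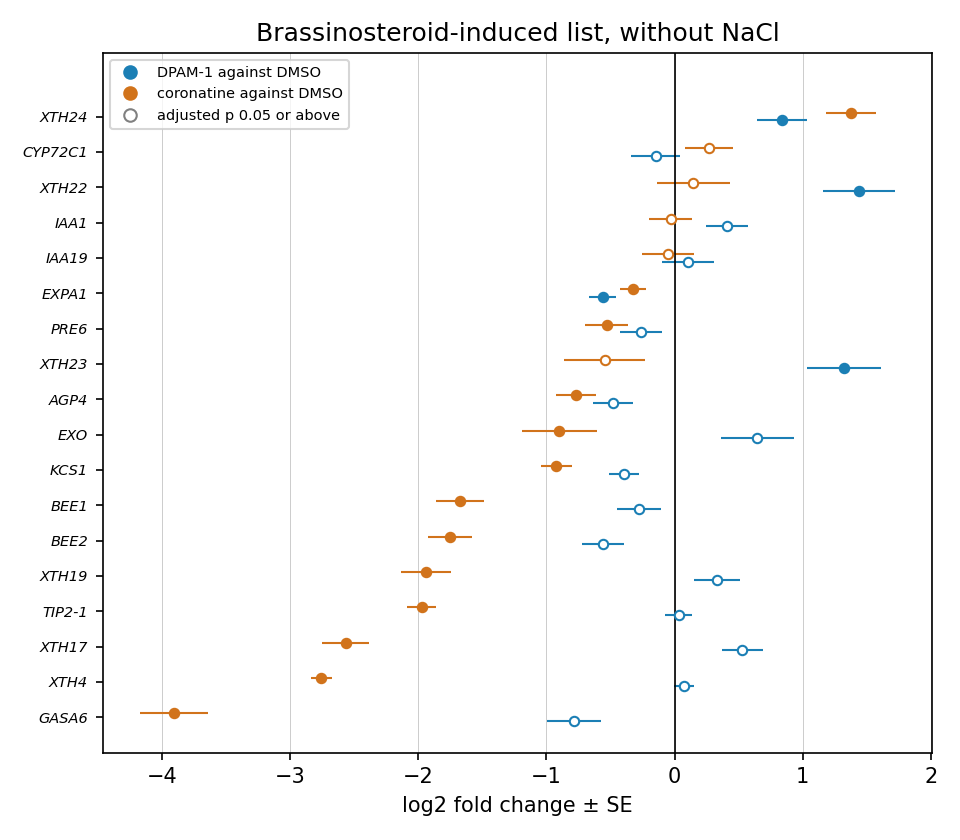
Log2 fold changes with SE (horizontal axis, n = 3 libraries per group) of the 18 brassinosteroid-induced genes (vertical axis) in DPAM-1 and in coronatine against DMSO without NaCl, with open points where the adjusted p was 0.05 or above. In DPAM-1 3 members are higher and 1 lower, and in coronatine 1 is higher and 12 lower.

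No jasmonate gene of the lists passed after DPAM-1. This covered 9 JAZ repressor genes (0 called by edgeR, 3 unadjusted, 1 by DESeq2). It also covered 17 jasmonate biosynthesis and catabolism genes (0, 7 and 0) and 12 jasmonate output genes (0, 3 and 1). Their medians were 0.31, 0.28 and 0.36, and adjusted over the list alone 2, 4 and 1 members were higher. Camera gave adjusted p = 0.00318, estimated-correlation p = 0.279 for the JAZ list, adjusted p = 2.6e-04, estimated-correlation p = 0.284 for biosynthesis and adjusted p = 0.0446, estimated-correlation p = 0.419 for output. Without DPAM-1 replicate 2 the JAZ value became 0.460 and the output list turned to the lower side at 0.637. The output value became 0.0651 without DMSO replicate 1 and 0.192 without DMSO replicate 2. VSP2 (AT5G24770), a vegetative storage protein gene used as a jasmonate marker, was at 0.34 ± 0.20, the lipoxygenase LOX2 (AT3G45140) at 0.28 ± 0.15 and the repressor JAZ10 (AT5G13220) at 0.31 ± 0.17, none past the threshold. Of 13 flavonoid and anthocyanin genes none passed over all genes (0 called by edgeR, 12 unadjusted, 4 by DESeq2). Adjusted over the list alone 12 were higher, median 0.44, camera adjusted p = 3.5e-09, estimated-correlation p = 0.171. Of 20 abscisic acid and osmotic stress genes none passed (0 called by edgeR, 5 unadjusted, 1 by DESeq2, 4 higher adjusted over the list alone, camera adjusted p = 0.0155, estimated-correlation p = 0.471). Of 10 sodium and potassium transport genes none passed (0, 2 and 0, camera adjusted p = 0.181, estimated-correlation p = 0.336). RD29A (AT5G52310), a gene induced by drought and salt, was at 0.65 ± 0.22 (adjusted p = 0.166) and SOS1 (AT2G01980), the plasma membrane sodium exporter, at -0.16 ± 0.19 (adjusted p = 0.758).

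In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 145 genes for DPAM-1 against DMSO, 114 higher and 31 lower, with 2021 genes at an unadjusted p under 0.05. DESeq2 called 308 (219 higher and 89 lower). The edgeR count fell to 90 without DMSO replicate 3, 88 without DPAM-1 replicate 1 and 76 without DPAM-1 replicate 3. The call of XTH24 ended whichever of the 6 libraries was left out (adjusted p up to 0.128), that of XTH23 with any of them but DPAM-1 replicate 3 (up to 0.0974).

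Coronatine against DMSO without NaCl asked for the response to the jasmonate mimic. Jasmonate genes rose steeply, VSP2 from 199 CPM ± 10.7 (SD, n = 3) to 6346 CPM ± 952 (SD, n = 3). LOX2 rose 23.9-fold, JAZ10 25.3-fold and MYC2 (AT1G32640), the master transcription factor of the pathway, 14.6-fold. AOS (AT5G42650), which makes the precursor of jasmonate, rose 22.8-fold to 1487 CPM ± 25.7 (SD, n = 3). CYP79B2 (AT4G39950) rose to a log2 fold change of 3.05 ± 0.09, adjusted p = 1.5e-17 and CYP79B3 (AT2G22330) to 3.42 ± 0.10, adjusted p = 1.7e-17, both P450 enzymes of glucosinolate synthesis that convert tryptophan. Flavonoid genes rose, such as DFR (AT5G42800) at 2.40 ± 0.14, adjusted p = 5.8e-13 and CHS (AT5G13930), chalcone synthase, at 1.90 ± 0.10, adjusted p = 8.9e-14. The wall enzyme genes XTH4 (AT2G06850) and XTH17 (AT1G65310) fell, 6.76-fold to 65.4 CPM ± 8.46 (SD, n = 3) and 5.93-fold. The tonoplast aquaporin TIP2-1 (AT3G16240) fell 3.93-fold and GASA6 (AT1G74670), a gibberellin-regulated gene, 15.0-fold. GSTF6 rose (log2 2.29 ± 0.09) while its near-identical neighbour GSTF7 fell (log2 -2.21 ± 0.14).

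Counted by list, 8 of 9 JAZ repressor genes rose by a median of 3.24 (8 adjusted over the list alone, camera adjusted p = 2.5e-12, estimated-correlation p = 0.0168). So did 16 of 17 jasmonate biosynthesis and catabolism genes, median 3.23 (16 over the list alone, camera adjusted p = 4.5e-22, estimated-correlation p = 0.0142). All 12 jasmonate output genes rose, median 3.80 (12 over the list alone, camera adjusted p = 9.2e-17, estimated-correlation p = 0.0142). Reads of the near-identical pairs VSP1 and VSP2 and of AOC1, AOC2 and AOC3 cannot be assigned with certainty within each set. Glucosinolate genes had 10 higher and 2 lower of 14 (the same counts over the list alone), camera adjusted p = 2.9e-07, estimated-correlation p = 0.0299. CYP83A1 (AT4G13770), of the aliphatic branch, was among those that fell (-0.67 ± 0.10, adjusted p = 6.2e-06). Of 13 flavonoid and anthocyanin genes 12 rose and FLS1 (AT5G08640), which makes flavonols, fell (-1.16 ± 0.10, adjusted p = 2.3e-09), camera adjusted p = 1.3e-10, estimated-correlation p = 0.107. All 6 early stress transcription factor genes rose (6 over the list alone), with ZAT10 at 2.53 ± 0.15, camera adjusted p = 7.1e-06, estimated-correlation p = 0.0142.

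Brassinosteroid-induced genes went down as a list: 12 of 18 fell and 1 rose (the same counts adjusted over the list alone), median -0.84, camera adjusted p = 1.8e-05, estimated-correlation p = 0.0299. Beside XTH4, XTH17, TIP2-1 and GASA6, which is also in the gibberellin list, the exception was XTH24, which rose (1.37 ± 0.20, adjusted p = 4.4e-06). Brassinosteroid biosynthesis genes moved both ways: DET2 (AT2G38050), the steroid reductase of the pathway, rose 2.57-fold to 48.9 CPM ± 6.03 (SD, n = 3) and CPD fell 1.46-fold. In this list of 7, 2 rose and 1 fell (3 and 1 over the list alone, camera adjusted p = 0.518, estimated-correlation p = 0.664), turned to 1 and 2 with library totals. Its median was 0.10 by TMM, -0.02 with upper-quartile factors and -0.13 with library totals. Of 10 brassinosteroid signalling genes 1 was higher and 2 were lower (1 and 2 over the list alone, camera adjusted p = 0.639, estimated-correlation p = 0.666). They included IBH1 (AT2G43060), a growth repressor, at 0.88 ± 0.18, adjusted p = 3.9e-04, and BES1 (AT1G19350), a transcription factor of the pathway, at -0.62 ± 0.08, adjusted p = 1.8e-06.

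Ethylene genes fell, 8 of 10 with 1 higher (the same over the list alone, camera adjusted p = 0.00431, estimated-correlation p = 0.0445). Abscisic acid and osmotic stress genes split into 10 higher and 4 lower of 20 (11 and 4 over the list alone, camera adjusted p = 0.0249, estimated-correlation p = 0.664), with the galactinol synthase GOLS1 (AT2G47180) at 4.13 ± 0.18 and RD22 (AT5G25610) at -2.23 ± 0.15. Cell division genes had 5 of 12 lower, such as PCNA1 (AT1G07370), the DNA replication clamp, at -0.56 ± 0.11 (7 over the list alone, camera adjusted p = 0.0215, estimated-correlation p = 0.125). Of 8 root hair genes 6 were higher, led by the expansin EXPA18 (AT1G62980) at 0.97 ± 0.14 (6 over the list alone, camera adjusted p = 0.0215, estimated-correlation p = 0.192). Of 7 endodermis genes, also of root tissue, 5 fell, including CASP2 (AT3G11550), a Casparian strip protein, at -0.71 ± 0.17 (5 over the list alone, camera adjusted p = 0.0795, estimated-correlation p = 0.480). Of 20 detoxification genes 7 rose and 10 fell, a median of -0.18 against a mean of 0.36 (camera adjusted p = 0.993, estimated-correlation p = 0.993). Sodium and potassium transport genes had 1 higher and 4 lower of 10, with the proton pump AHA2 (AT4G30190) at -1.40 ± 0.13 (camera adjusted p = 0.209, estimated-correlation p = 0.434). Auxin response genes had 3 higher and 1 lower of 8, with median -0.04 and mean 0.28 (camera adjusted p = 0.510, estimated-correlation p = 0.666). Gibberellin genes had 2 higher and 3 lower of 6 (camera adjusted p = 0.610, estimated-correlation p = 0.666). Salicylic acid defence genes had 1 higher, EDS5 (AT4G39030), and 1 lower, EDS1 (AT3G48090), of 4, with median -0.33 and mean 0.12 (camera adjusted p = 0.993, estimated-correlation p = 0.993). Iron deficiency genes had 3 lower of 7, among them the transporter OPT3 (AT4G16370) at -0.60 ± 0.08 (camera adjusted p = 0.124, estimated-correlation p = 0.192). Hypoxia genes had 1 higher and 4 lower of 9 (camera adjusted p = 0.461, estimated-correlation p = 0.666). Clock genes had 1 higher and 1 lower of 8 with a median of 0.01, which turned to -0.10 and -0.22 with upper-quartile factors and library totals (camera adjusted p = 0.993, estimated-correlation p = 0.993). Photosynthesis genes had 8 higher and 3 lower of 26, which turned to 3 higher and 8 lower with library totals (camera adjusted p = 0.125, estimated-correlation p = 0.689). Heat shock and guard cell genes, 3 measured in each, had 0 called by edgeR (unadjusted 0 and 1, DESeq2 0 and 1). Camera gave adjusted p = 0.733, estimated-correlation p = 0.740 for heat shock and adjusted p = 0.694, estimated-correlation p = 0.703 for guard cells. Among 5 touch genes the calmodulin-like CML39 (AT1G76640) rose (4.79 ± 0.24) and CML9 (AT3G51920) fell (-0.87 ± 0.11), with a median of -0.19 against a mean of 0.69 (camera adjusted p = 0.993, estimated-correlation p = 0.993).

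**Figure D3:**
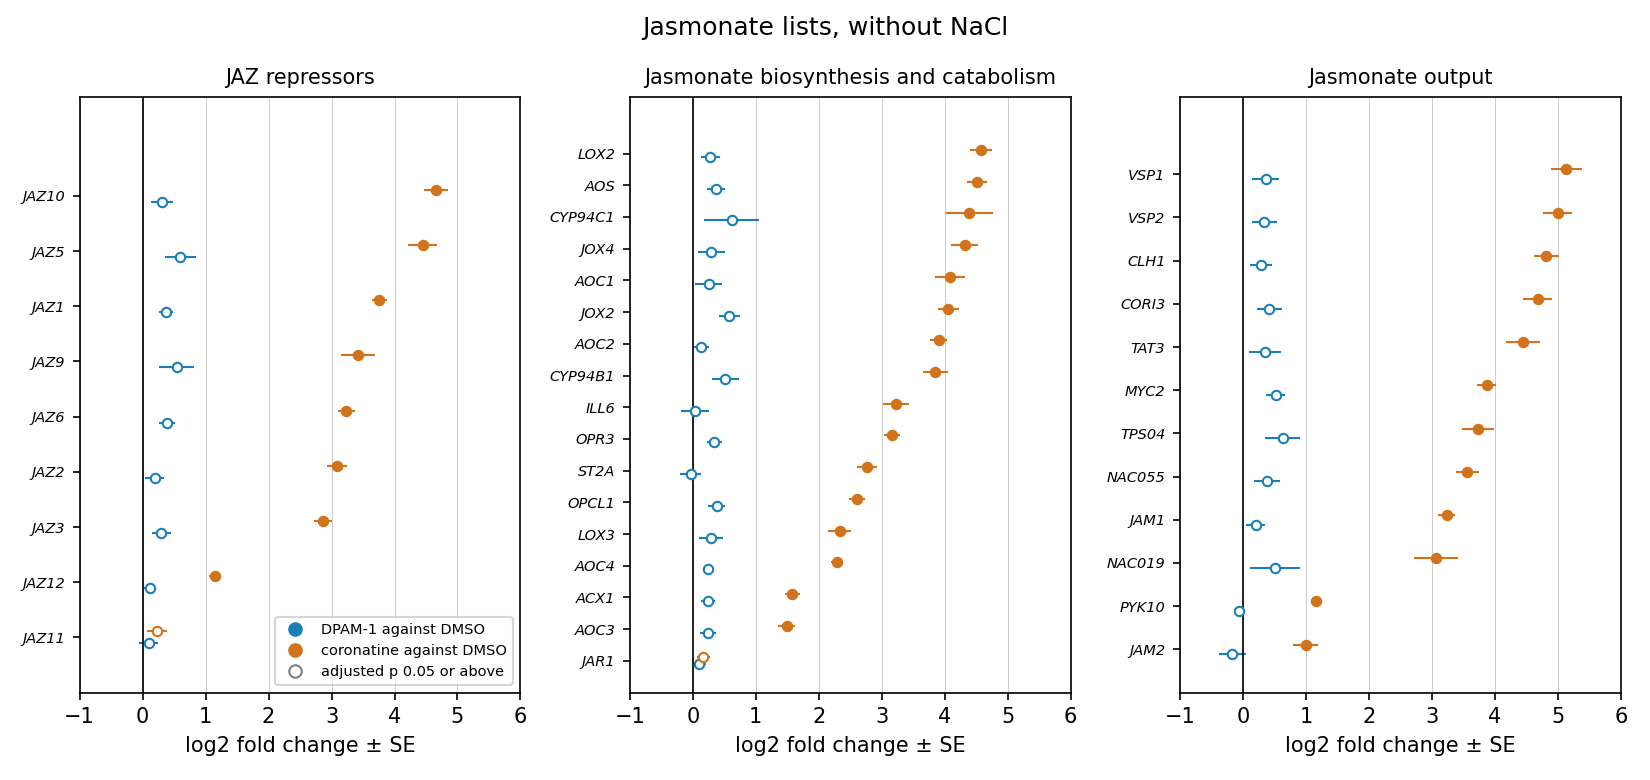
Log2 fold changes with SE (horizontal axes, n = 3 libraries per group) of the JAZ, jasmonate biosynthesis and catabolism, and jasmonate output genes (vertical axes, 1 panel per list) for DPAM-1 and coronatine against DMSO without NaCl, with open points where the adjusted p was 0.05 or above. The JAZ median is 0.31 in DPAM-1 and 3.24 in coronatine, and all DPAM-1 points are open.

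By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4947 genes passed for coronatine, 2477 higher and 2470 lower. By TMM 50.1% of the calls were higher. With upper-quartile factors the median of all genes lay at -0.13 and 32.5% of 5611 calls were higher. With library totals it lay at -0.24 and 20.7% of 7272 were higher. Same-numbered DMSO and coronatine libraries deviated together, those numbered 3 most, and the fit with the number as a block gave 4900 genes, or 5431 from these 6 libraries alone. Groups overlapped in 5 of the 107 named genes that passed. Genes named by size were picked for groups that do not overlap, and list members for a small p. Here and in the other comparisons such counts are therefore low by selection and do not describe all called genes.

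The compounds were then compared with each other at the same dose and time. Jasmonate genes were far lower after DPAM-1 than after coronatine: VSP2 25.3-fold, JAZ10 20.4-fold and LOX2 19.7-fold. XTH4 was higher after DPAM-1, at 465 CPM ± 21.2 (SD, n = 3) against 65.4 CPM ± 8.46 (SD, n = 3), and so were XTH17, 8.57-fold, and GASA6, 8.71-fold. TCH3 was 4.81-fold and XTH22 2.45-fold higher after DPAM-1, and so was WRKY33, 1.58-fold, whereas ZAT10 was 2.34-fold lower. RD29A was 2.43-fold higher after DPAM-1 (log2 1.28 ± 0.22, adjusted p = 6.2e-05).

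Of 18 brassinosteroid-induced genes 12 were higher after DPAM-1 than after coronatine and 1 was lower (12 and 3 adjusted over the list alone, camera adjusted p = 8.8e-06, estimated-correlation p = 0.0396). All 12 jasmonate output genes, 16 of 17 biosynthesis genes and 8 of 9 JAZ genes were lower (the same counts over each list alone), with camera adjusted p = 1.8e-16, estimated-correlation p = 0.0246 for the output list. Flavonoid genes had 12 of 13 lower and FLS1 higher (1.46 ± 0.10, adjusted p = 4.4e-11), camera adjusted p = 2.4e-08, estimated-correlation p = 0.173. Of 6 early stress genes 5 were lower and WRKY33 was higher, camera adjusted p = 0.00186, estimated-correlation p = 0.0488. Hypoxia genes had 5 of 9 higher, such as alcohol dehydrogenase ADH1 (AT1G77120) at 0.92 ± 0.15 (6 over the list alone, camera adjusted p = 0.0154, estimated-correlation p = 0.195). Of 7 endodermis genes 5 were higher (5 over the list alone, camera adjusted p = 0.0117, estimated-correlation p = 0.242). Brassinosteroid biosynthesis genes gave 1 higher and 2 lower, turned to 2 and 1 with library totals. Signalling genes gave 2 higher and 3 lower, turned to 3 and 1 with upper-quartile factors and 4 and 0 with library totals. Photosynthesis genes gave 3 higher and 4 lower, turned to 7 and 2 and to 15 and 2. IAA19 did not pass, with a 95% interval of the difference from -0.26 to 0.58, and neither did DWF4 (-0.74 to -0.08). The edgeR test called 4961 genes, 2475 higher and 2486 lower after DPAM-1. Groups overlapped in 1 of the 112 named genes that passed. Of the other 9268 genes of the table, 98.9% had a 95% interval within 1 log2 unit of no difference. The share of higher calls moved from 49.9% to 63.0% with upper-quartile factors and to 76.7% with library totals, where the median of all genes was 0.08 and 0.19.

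Genes changed by both compounds against DMSO were counted next. There were 69 in the same direction, 49 higher (19.8 expected by chance) and 20 lower (5.38 expected). Another 34 changed in opposite directions, 31 higher with DPAM-1 and lower with coronatine (19.8 expected) and 3 the other way (5.40 expected). Both comparisons use the same 3 DMSO libraries, which alone makes their errors agree and which are too few to divide. In 20 simulations of unchanged groups against those libraries the highest count shared was 0, but at most 1 gene was called in a comparison, so this does not measure what shared errors add to lists of this size. Part of the excess may come from the shared libraries. The covariance of the fold changes across genes was 0.0397 against 0.0119 on average in the simulations, a difference of 0.0278. The correlation was 0.25 against 0.499 in the simulations, where no true changes widen the fold changes. Genes are not independent replicates. DESeq2 gave 144 shared genes, and leaving out 1 library gave 39 (DMSO replicate 3), 42, 40 and 36 (DPAM-1 replicates 1, 2 and 3) or 116 (coronatine replicate 3).

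NaCl against no NaCl in DMSO gave the salt response without a compound, with any effect of the addition itself included. Within 2 h RD29A rose 5.79-fold to 133 CPM ± 61.0 (SD, n = 3), the dehydrin ERD10 (AT1G20450) 2.76-fold and the abscisic acid-responsive transcription factor HB7 (AT2G46680) 4.52-fold. The largest rises among named genes with a symbol were those of DIP2 (AT5G03210) at 3.69 ± 0.28, ZAT12 at 3.47 ± 0.21 and ZAT10 at 3.38 ± 0.15, ZAT10 reaching 60.6 CPM ± 7.64 (SD, n = 3). XTH22 rose 4.78-fold and EXPA1 3.44-fold, while XTH17 fell 3.32-fold and FLA9 (AT1G03870), a fasciclin-like arabinogalactan protein gene, changed by -1.85 ± 0.14. The ethylene synthesis gene ACS6 (AT4G11280) rose 5.92-fold and the auxin-conjugating enzyme gene GH3.3 (AT2G23170) 4.67-fold.

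By list, 18 of 20 abscisic acid and osmotic stress genes rose and none fell (18 adjusted over the list alone), median 1.16, camera adjusted p = 8.3e-17, estimated-correlation p = 0.0662. KIN1 and KIN2, near-identical, are both in it. Early stress transcription factor genes had 5 of 6 higher (5 over the list alone, camera adjusted p = 2.0e-07, estimated-correlation p = 0.00546). Detoxification genes had 18 of 20 higher (20 over the list alone, camera adjusted p = 2.9e-17, estimated-correlation p = 0.00546). Of 17 jasmonate biosynthesis genes 12 rose (15 over the list alone, camera adjusted p = 3.2e-09, estimated-correlation p = 0.114). So did 6 of 9 JAZ genes (6 over the list alone, camera adjusted p = 3.0e-04, estimated-correlation p = 0.197), with MYC2 at 1.58 ± 0.15, adjusted p = 5.3e-08. Touch genes had 3 of 5 higher (4 over the list alone, camera adjusted p = 3.0e-04, estimated-correlation p = 0.0347). Hypoxia genes had 4 of 9 lower (5 over the list alone, camera adjusted p = 0.0293, estimated-correlation p = 0.321), and cell division genes 4 of 12 lower (4 over the list alone, camera adjusted p = 0.00958, estimated-correlation p = 0.114). Sodium and potassium transport genes had 3 higher and 2 lower of 10 (4 and 2 over the list alone, camera adjusted p = 0.309, estimated-correlation p = 0.509). The vacuolar exchanger NHX2 (AT3G05030) was at 1.31 ± 0.20, adjusted p = 5.0e-05 and SOS1 at 0.21 ± 0.18 (adjusted p = 0.468). Brassinosteroid-induced genes split evenly, 5 higher and 5 lower (5 and 6 over the list alone), with a median of -0.05 against a mean of 0.12 (camera adjusted p = 0.656, estimated-correlation p = 0.787). In all 2516 genes passed edgeR's test, 1395 higher and 1121 lower, and 1677 without DMSO with NaCl replicate 3. Groups overlapped in 5 of the 80 named genes that passed.

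NaCl against no NaCl in DPAM-1 gave the salt response after the compound. RD29A rose 4.70-fold to 169 CPM ± 35.2 (SD, n = 3), ERD10 2.37-fold and HB7 4.29-fold, while ZAT10 rose 1.84-fold and WRKY33 1.73-fold. XTH22 went down, from 43.1 CPM ± 1.28 (SD, n = 3) to 20.3 CPM ± 10.4 (SD, n = 3) (log2 -1.09 ± 0.28, adjusted p = 0.00980), a call that ended without DPAM-1 with NaCl replicate 1 or 2 (adjusted p up to 0.0683). EXPA1 rose 4.24-fold and EXPA10 (AT1G26770), another expansin, 5.53-fold, and XTH17 fell 3.96-fold. Of 20 abscisic acid and osmotic stress genes 17 rose (18 adjusted over the list alone, camera adjusted p = 3.1e-23, estimated-correlation p = 0.0383). Early stress genes had 4 higher and 1 lower, AZF3 (AT5G43170) at -0.88 ± 0.16, adjusted p = 5.5e-04 (the same over the list alone, camera adjusted p = 0.106, estimated-correlation p = 0.274). Brassinosteroid-induced genes had 8 of 18 lower and 1 higher, EXPA1 (9 and 2 over the list alone, camera adjusted p = 7.6e-04, estimated-correlation p = 0.0883). Hypoxia genes had 6 of 9 lower, such as PCO1 (AT5G15120), an oxygen-sensing oxidase, at -1.35 ± 0.21 (6 over the list alone, camera adjusted p = 1.9e-05, estimated-correlation p = 0.0436). Gibberellin genes had 4 of 6 higher (4 over the list alone, camera adjusted p = 0.00241, estimated-correlation p = 0.0383). Touch genes had 1 higher and 3 lower of 5 (2 and 3 over the list alone, camera adjusted p = 0.373, estimated-correlation p = 0.575). Photosynthesis genes had 0 higher and 1 lower, turned to 2 and 1 with library totals. By edgeR 1742 genes passed, 984 higher and 758 lower, with overlapping groups in 2 of the 79 named ones. Lists called here and in DMSO are not thereby shown to differ or to match, which the interaction tests.

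**Figure D4:**
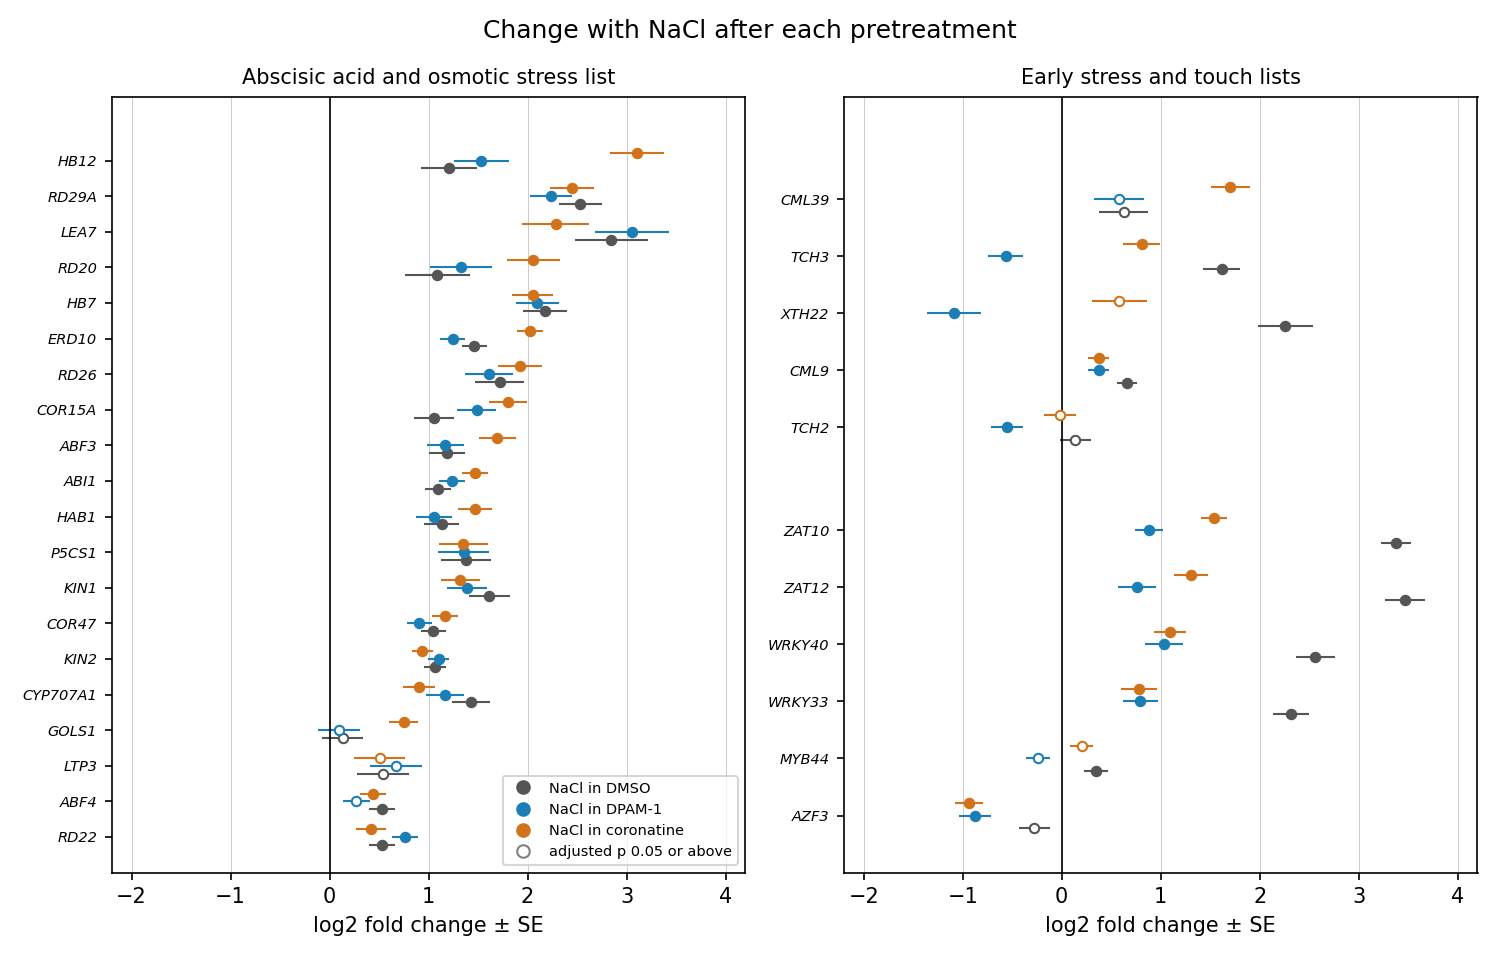
Log2 fold changes by NaCl with SE (horizontal axes, n = 3 libraries per group) of the abscisic acid and osmotic stress genes (first panel) and the early stress and touch genes (second panel) in DMSO, DPAM-1 and coronatine, with open points where the adjusted p was 0.05 or above. The abscisic acid medians are 1.16, 1.24 and 1.47 in that order, and the early stress medians 2.44, 0.78 and 0.94.

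Salt after coronatine raised the abscisic acid list again, 19 of 20 (19 adjusted over the list alone, camera adjusted p = 2.6e-19, estimated-correlation p = 0.0780). RD29A was 5.47-fold higher at 80.8 CPM ± 10.5 (SD, n = 3) and the transcription factor HB12 (AT3G61890) 8.61-fold higher. DIP2 rose 31.9-fold, the methionine gamma-lyase MGL (AT1G64660) 6.27-fold and GSTU5 (AT2G29450), a glutathione transferase, 2.76-fold. GH3.3 fell 2.30-fold. Jasmonate output genes had 7 of 12 higher (8 over the list alone, camera adjusted p = 1.6e-06, estimated-correlation p = 0.139), among them NAC055 (AT3G15500), a stress transcription factor, at 1.43 ± 0.14. Biosynthesis genes had 13 of 17 higher (13 over the list alone, camera adjusted p = 1.4e-07, estimated-correlation p = 0.139). Glucosinolate genes had 8 lower and 2 higher of 14 (10 and 3 over the list alone, camera adjusted p = 6.9e-04, estimated-correlation p = 0.139), including CYP79B2 at -0.93 ± 0.08. Detoxification genes had 15 of 20 higher (15 over the list alone, camera adjusted p = 2.9e-09, estimated-correlation p = 0.0677), and DET2 rose 1.83-fold. The medians of the flavonoid, sodium transport, ethylene and gibberellin lists changed sign with library totals (2 higher and 4 lower sodium transport genes against 2 and 2). Photosynthesis genes went from 8 higher and 4 lower to 3 and 4. In edgeR's test 3811 genes passed, 2095 higher and 1716 lower. The higher share was 42.8% with upper-quartile factors and 32.3% with library totals. In 2 of the 92 named genes that passed the groups overlapped.

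**Figure D5:**
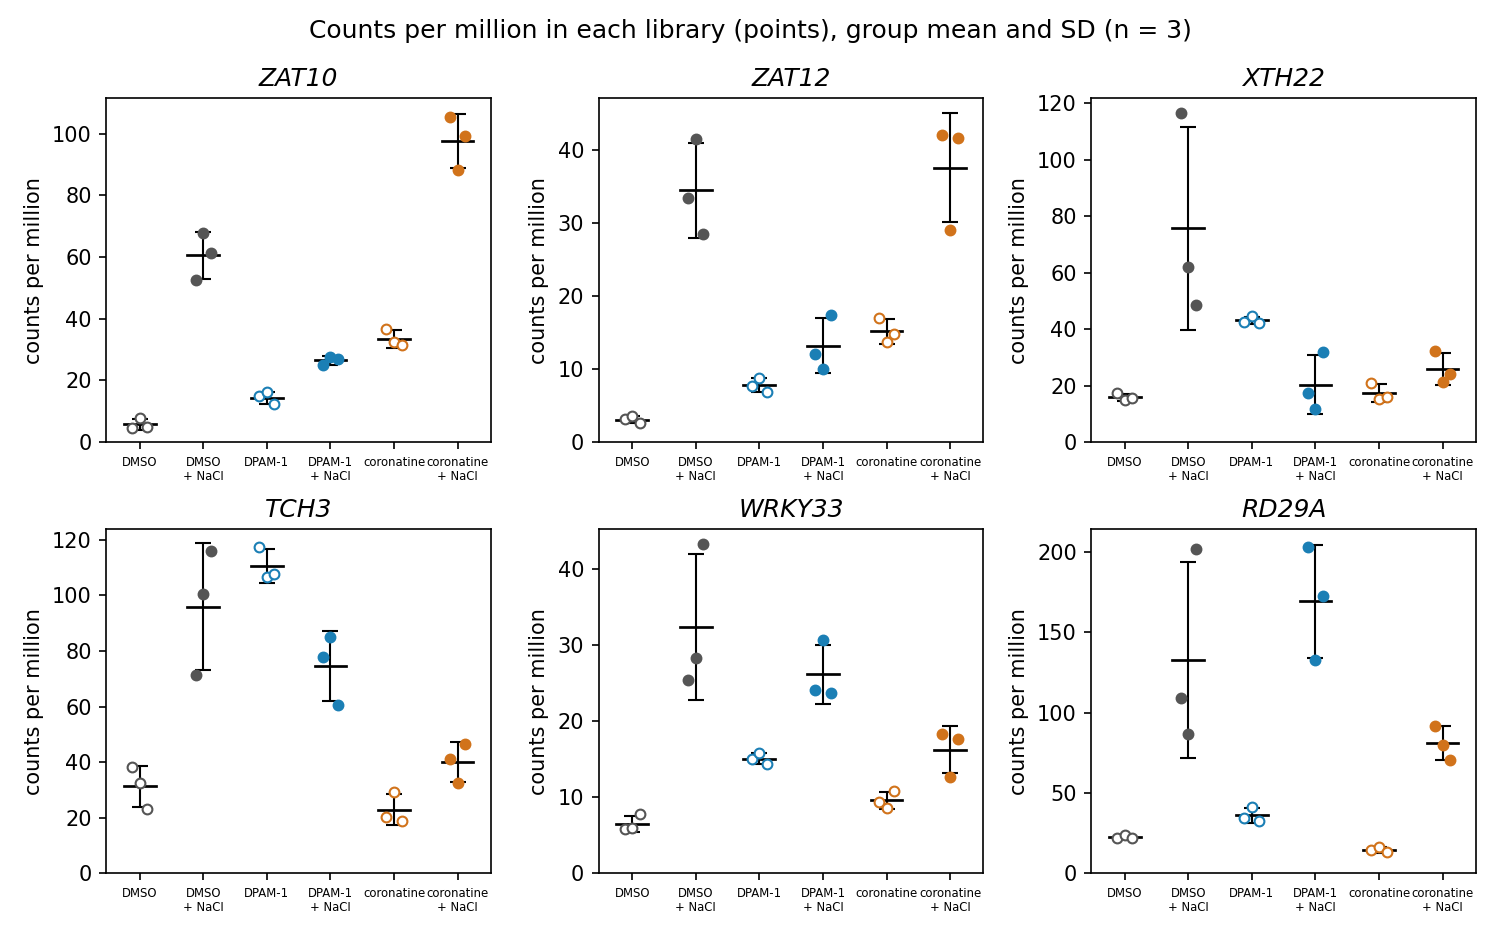
CPM (vertical axes) of ZAT10, ZAT12, XTH22, TCH3, WRKY33 and RD29A in each of the 18 libraries (points), by group (horizontal axis), with bars for the mean and SD of 3 libraries. XTH22 averages 15.9 CPM ± 1.24 in DMSO, 75.6 CPM ± 36.0 in DMSO with NaCl, 43.1 CPM ± 1.28 in DPAM-1 and 20.3 CPM ± 10.4 in DPAM-1 with NaCl.

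The interaction of DPAM-1 with NaCl tested whether salt changed genes by a different amount after DPAM-1 than after DMSO. Among the genes with a lower salt effect after DPAM-1, XTH22 differed most, by -3.35 ± 0.39, adjusted p = 3.4e-05. Salt took it from 15.9 CPM ± 1.24 to 75.6 CPM ± 36.0 (SD, n = 3) in DMSO and from 43.1 CPM ± 1.28 to 20.3 CPM ± 10.4 (SD, n = 3) after DPAM-1. ZAT12 differed by -2.70 ± 0.28, adjusted p = 8.9e-06, ZAT10 by -2.49 ± 0.21, adjusted p = 2.1e-07, TCH3 by -2.18 ± 0.26, adjusted p = 3.4e-05 and WRKY33 by -1.52 ± 0.25, adjusted p = 0.00259. MYC2 differed by -1.23 ± 0.21, adjusted p = 0.00259 and ACS6 by -1.36 ± 0.24, adjusted p = 0.00425. The 1 gene raised more was the expansin EXPA11 (AT1G20190), at 0.77 ± 0.15, adjusted p = 0.0110, a call that ended without DPAM-1 with NaCl replicate 1 (0.0517).

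Of 6 early stress genes 4 were lower in this test (6 adjusted over the list alone), median -1.52, camera adjusted p = 2.2e-20, estimated-correlation p = 6.7e-05. Of 5 touch genes 2 were lower (3 over the list alone, camera adjusted p = 3.0e-10, estimated-correlation p = 9.3e-04). Detoxification genes had 1 lower, OPR1 at -1.01 ± 0.16, adjusted p = 0.00135 (5 over the list alone, camera adjusted p = 8.2e-10, estimated-correlation p = 0.0218). Brassinosteroid-induced genes had 4 of 18 lower, XTH22, XTH23 at -2.66 ± 0.40, XTH24 at -1.48 ± 0.28 and EXO (AT4G08950), a growth gene, at -2.22 ± 0.41 (1 higher and 4 lower over the list alone, camera adjusted p = 0.00222, estimated-correlation p = 0.149). EXO was at -1.42 without DMSO with NaCl replicate 1. The abscisic acid list gave no call by edgeR (0 of 20, 0 unadjusted, 0 by DESeq2). Its median was -0.03 while the test pointed up (camera adjusted p = 0.702, estimated-correlation p = 0.902), and its camera adjusted p was 1.6e-04 without DMSO with NaCl replicate 3. RD29A was at -0.30 ± 0.29, with a 95% interval of -0.91 to 0.30. Sodium and potassium transport genes gave 0 of 10 (0 unadjusted, 0 by DESeq2, camera adjusted p = 0.176, estimated-correlation p = 0.407). SOS1 was at 0.25 ± 0.26 (95% interval -0.29 to 0.79). In all 71 genes passed edgeR's test, 1 higher and 70 lower, of 809 at an unadjusted p under 0.05. Tested on simulated changes, this contrast recovered 28.4% of 1.5-fold, 77.6% of 2-fold and all of 4-fold differences, so differences under 2-fold were often missed.

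The interaction of coronatine with NaCl asked the same of coronatine. GH3.3, raised by salt in DMSO and lowered after coronatine, differed by -3.42 ± 0.26, adjusted p = 6.2e-08, and the ethylene response factor genes ERF2 (AT5G47220) and ERF-1 (AT4G17500) by -3.05 ± 0.40, adjusted p = 6.6e-05 and -2.26 ± 0.28, adjusted p = 3.5e-05. ZAT12 differed by -2.16 ± 0.27, adjusted p = 3.7e-05, ZAT10 by -1.84 ± 0.20, adjusted p = 9.7e-06 and WRKY33 by -1.54 ± 0.26, adjusted p = 9.7e-04. Raised more by salt after coronatine were UGT76E12 (AT3G46660), a glycosyltransferase, at 2.77 ± 0.39, adjusted p = 1.5e-04, PPCK2 (AT3G04530), a carboxylase kinase, at 2.01 ± 0.34, adjusted p = 9.7e-04 and HB12 at 1.90 ± 0.39, adjusted p = 0.00570. Early stress genes had 4 of 6 lower (5 adjusted over the list alone, camera adjusted p = 3.2e-08, estimated-correlation p = 0.00436). The abscisic acid list had 1 higher of 20, HB12 (2 over the list alone, camera adjusted p = 0.132, estimated-correlation p = 0.660, 1.2e-05 without DMSO with NaCl replicate 3). Its median was 0.05 and became -0.05 with library totals. The medians of the brassinosteroid biosynthesis, ethylene and iron lists also changed sign with the scaling. By edgeR 546 genes passed, 237 higher and 309 lower. The higher share was 43.4% by TMM, 32.9% with upper-quartile factors and 22.6% with library totals, and 359 genes passed without coronatine with NaCl replicate 1. Both interactions use the same DMSO groups.

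Under NaCl, DPAM-1 against DMSO compared salt-treated seedlings directly. ZAT10 stood at 26.5 CPM ± 1.42 (SD, n = 3) after DPAM-1 against 60.6 CPM ± 7.64 (SD, n = 3) in DMSO. ZAT12 was 2.61-fold, XTH22 3.74-fold and ACS6 2.05-fold lower. Higher after DPAM-1 were AT2G44130, 3.72-fold, and COR15A (AT2G42540), a cold- and drought-induced chloroplast protein gene, 2.07-fold. The COR15A call ended without DPAM-1 with NaCl replicate 1 (0.0532). Brassinosteroid-induced genes had 3 of 18 lower and none higher, XTH22, EXO and XTH23 (7 lower over the list alone, camera adjusted p = 8.7e-06, estimated-correlation p = 0.0450). EXO and XTH23 did not pass when only these 6 libraries were fitted (0.122 and 0.132), and EXO was at -0.77 without DMSO with NaCl replicate 1. Early stress genes had 2 of 6 lower (4 over the list alone, camera adjusted p = 1.8e-09, estimated-correlation p = 0.00313), and touch genes 1 of 5 (2 over the list alone, camera adjusted p = 0.00702, estimated-correlation p = 0.0755). Of 8 root hair genes PRP3 was again lower, at -0.50 ± 0.10, adjusted p = 0.0156 (2 over the list alone, camera adjusted p = 0.251, estimated-correlation p = 0.544), a call that ended without DMSO with NaCl replicate 1 or 3 or DPAM-1 with NaCl replicate 1 or 2 (up to 0.107). Clock genes had 0 called by edgeR (4 unadjusted, 2 by DESeq2) with 4 of 8 lower over the list alone, camera adjusted p = 8.6e-05, estimated-correlation p = 0.0450. Flavonoid genes gave 0 called by edgeR (9 unadjusted, 3 by DESeq2) and 8 of 13 higher over the list alone, camera adjusted p = 3.8e-10, estimated-correlation p = 0.105. RD29A was at 0.35 ± 0.20 (95% interval -0.06 to 0.76) and SOS1 at 0.09 ± 0.18 (-0.29 to 0.46). The medians of the JAZ, detoxification, heat shock, gibberellin and brassinosteroid biosynthesis lists lay so near 0 that another scaling turned their sign. By edgeR 82 genes passed, 25 higher and 57 lower, with 195 by DESeq2 (91 and 104) and 47 from these 6 libraries alone. The count was 144 without DMSO with NaCl replicate 3, and 35 and 37 without DPAM-1 with NaCl replicate 1 and 2. Groups overlapped in 1 of the 20 named genes that passed, XTH23.

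Coronatine against DMSO under NaCl again raised jasmonate genes, with VSP2 at 8668 CPM ± 276 (SD, n = 3) against 175 CPM ± 1.84 (SD, n = 3). All 9 JAZ and all 12 output genes were higher (the same over each list alone, camera adjusted p = 3.0e-10, estimated-correlation p = 0.0423 and adjusted p = 1.6e-14, estimated-correlation p = 0.0423). Brassinosteroid-induced genes had 14 of 18 lower and 3 higher (the same over the list alone, camera adjusted p = 7.6e-05, estimated-correlation p = 0.0567), with XTH4 at -2.62 ± 0.08 and XTH24 at 0.96 ± 0.19. DET2 was 4.11-fold higher and CPD 1.86-fold lower, in a biosynthesis list of 3 higher and 1 lower that turned to 1 and 3 with library totals. RD29A was 1.64-fold lower, at -0.71 ± 0.20, and at -0.28 without DMSO with NaCl replicate 3, where it did not pass (0.123). The auxin list (4 higher and 3 lower), photosynthesis (9 and 5), root hair (3 and 0) and endodermis (1 and 0) lists turned to mostly lower with library totals (1 and 4, 5 and 16, 2 and 3, 0 and 6). By edgeR 6808 genes passed, 3390 higher and 3418 lower. Groups overlapped in 1 of the 114 named genes that passed, RD29A. Of all calls 49.8% were higher by TMM, against 30.2% of 7534 with upper-quartile factors (median of all genes -0.17) and a still lower share of 9195 with library totals (median -0.34).

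DPAM-1 against coronatine under NaCl gave 6026 genes by edgeR, 2978 higher and 3048 lower after DPAM-1. Among the 116 named ones that passed, 1 had overlapping groups. VSP2 was 38.6-fold and ZAT10 3.70-fold lower after DPAM-1, and XTH4 was 5.90-fold, RD29A 2.09-fold and NHX2 (AT3G05030) 2.23-fold higher. Of 18 brassinosteroid-induced genes 11 were higher and 3 lower (12 and 3 over the list alone, camera adjusted p = 0.00302, estimated-correlation p = 0.168), and of 10 sodium and potassium transport genes 5 were higher (5 over the list alone, camera adjusted p = 0.0505, estimated-correlation p = 0.229). SOS1 did not pass (95% interval of the difference -0.55 to 0.20), nor did DWF4 (-0.15 to 0.53). DWF1 (AT3G19820), a reductase of brassinosteroid synthesis, was at -0.24 ± 0.07 by TMM and at 0.07 with library totals, where it did not pass. Photosynthesis genes went from 5 higher and 7 lower by TMM to 9 and 5 with upper-quartile factors and 18 and 1 with library totals. The brassinosteroid biosynthesis, auxin, clock, guard cell and touch medians also changed sign with a scaling. The higher share was 49.4% by TMM, 68.3% with upper-quartile factors and 82.1% with library totals, where the median of all genes lay at 0.15 and 0.31.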

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

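The interactions were planned, and the tests of depth and of a few abundant genes were set before they were run. The abundant-gene test uses library totals, a scaling otherwise added after the data had been seen. The tests by level under NaCl, touch genes, chloroplast and photosynthesis genes and regroupings were chosen after the result was seen.

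The effect of NaCl differed between compounds in tests of the difference itself. It differed between DPAM-1 and DMSO for 71 genes and between coronatine and DMSO for 546 in edgeR's quasi-likelihood test. For DPAM-1 the early stress transcription factor list (camera adjusted p = 2.2e-20), the touch list (3.0e-10), the detoxification list (8.2e-10), the JAZ list (0.00131), the brassinosteroid-induced list (0.00222), the auxin list (0.0126), the jasmonate biosynthesis and hypoxia lists (0.0191 each) and the photosynthesis list (0.0476) had a lower NaCl effect than in DMSO, and the guard cell list a higher one (0.0126). The NaCl effect on the hypoxia list had medians of -0.43 in DMSO (estimated-correlation p = 0.321) and -0.96 in DPAM-1 (0.0436). In the interaction the hypoxia, photosynthesis, jasmonate biosynthesis, auxin and guard cell lists had 0 members called by edgeR (0, 0, 4, 1 and 1 unadjusted) and 0 by DESeq2. With an estimated correlation the adjusted p of the early stress list was 6.7e-05, of the touch list 9.3e-04 and of the detoxification list 0.0218, while those of the JAZ (0.292), brassinosteroid-induced (0.149), auxin (0.212), jasmonate biosynthesis (0.530), hypoxia (0.306), photosynthesis (0.682) and guard cell (0.0741) lists lay over 0.05. For coronatine the early stress list differed (3.2e-08, and 0.00436 with an estimated correlation).

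Among genes, the differences for DPAM-1 were 0.77 for EXPA11 and, on the lower side, -3.35 for XTH22, -2.98 for AT1G07135, -2.70 for ZAT12, -2.67 for AT4G27280, -2.66 for XTH23 and -2.55 for ERF104 (AT5G61600), an ethylene response factor gene, all in log2 units. For coronatine, genes raised more by NaCl were UGT76E12 (2.77), PPCK2 (2.01), AT1G10530 (2.00), HB12 (1.90), AT5G04120 (1.71) and AT3G43270 (1.71), and those raised less or lowered were GH3.3 (-3.42), ERF2 (-3.05), SPX1 (AT5G20150), a phosphate-sensing gene (-2.47), AT3G15450 (-2.44), ERF-1 (-2.26) and AT5G61590 (-2.23, and -1.45 without DMSO with NaCl replicate 1).

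The first pattern is that 70 genes, ZAT10, ZAT12 and XTH22 among them, had a lower NaCl effect after DPAM-1 than after DMSO. Their median log2 fold change by NaCl was 1.57 in DMSO and 0.05 in DPAM-1, and without NaCl their median in DPAM-1 against DMSO, a difference the interaction contains, was 0.64, with 28 of the 70 called higher. Their median in the coronatine interaction was -1.02, with 41 of the 70 called lower. That interaction rests on the same DMSO libraries, so picking the genes shifts it below 0 without any effect of coronatine, and a deviation of these libraries stays open. Their level under NaCl lay below that of DMSO by a median of -0.72 and in 69 of the 70. Picking by the interaction shifts this median down, so it does not decide whether a raised level before NaCl was the only cause. The early stress list, fixed beforehand, also lay lower under NaCl (median -0.47, camera adjusted p = 1.8e-09), with 2 of 6 members called. For that list the values argue against a raised level as the only cause. But 4 of its 6 members are among the 70, so it is not separate support for the other genes. Lower depth is argued against by the 63 interaction genes that were still called with every library thinned to the smallest library total. Handling at harvest stays open, as the touch list had a median of 0.36 in DPAM-1 without NaCl, and an earlier response to DPAM-1 that dampens a later one may also explain the pattern but was not tested.

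The second pattern is that the DMSO and coronatine libraries numbered 3 deviated from their groups in the same way, 101 genes above 0.4 log2 units in both, 28 below in both and 3 opposite. A different share of shoot and root stays open. The photosynthesis and root hair lists deviated by medians of -0.133 and -0.126 in the DMSO library and -0.014 and 9.1e-04 in the coronatine library, and root hair members went both ways (3 and 4 of 8 above 0). RNA quality or priming also stays open. Chloroplast transcripts deviated by a median of 0.167 in the DMSO library and 0.351 in the coronatine library. In the libraries of these 2 groups numbered 1 and 2 the medians lay at -0.209 to 0.0593, in part because deviations from a group mean balance out. The share of organelle reads varied more in DMSO with NaCl (SD 0.259%) and DPAM-1 with NaCl (0.317%) than in DMSO (0.0835%) and coronatine (0.108%). Such variation is thus not particular to the libraries numbered 3. RNA quality or priming cannot be told apart from a shared day of preparation. No biological explanation was tested.

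The third pattern is that the share of lower calls after coronatine rose with upper-quartile factors and with library totals. With RLE factors 853 of the 854 results for named genes, over all comparisons, were the same as by TMM. That 20 abundant genes gaining 6.18% of the reads, such as VSP2 and BGLU18 (AT1G52400), were the whole cause is argued against by the median of all genes, which was -0.141 without them and -0.231 with them, on library totals. The amount of RNA per seedling, which relative counts do not show, is the same for all scalings and cannot explain their difference. It bears on the true share of lower calls, which stays open and untested.

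Regroupings asked how often other groupings of the same libraries give as many genes. With 3 libraries against 3 there are 10 groupings, so the share of groupings cannot go under 0.1, and in each such comparison the real one was the 1 grouping with the most calls. Each other grouping mixes the 2 real groups, so real differences enter the spread within its groups and a low count is built in. The low counts therefore do not tell whether chance can be excluded. The highest other count was 0 beside 145, 4947 and 4961 without NaCl, beside 2516 and 3811 for NaCl in DMSO and coronatine and beside 6808 and 6026 under NaCl, and it was 9 beside 1742 for NaCl in DPAM-1 and 9 beside 82 for DPAM-1 against DMSO under NaCl. For coronatine against DMSO, where the numbers may pair the libraries, the 3 other groupings that part each same-numbered pair also gave 0. For the interactions 40 groupings were drawn, the real one included: 2 of 40 gave at least the 71 genes of DPAM-1 (highest other 332) and 5 of 40 at least the 546 of coronatine (highest other 7677). Both highest counts came from the grouping that exchanged the compounds in the libraries without NaCl and not in those with NaCl. Such an exchange carries the compound effect itself into the interaction, so the counts do not tell whether chance can be excluded.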

How the results depend on the processing

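The tests with a mean count of at least 100, with library totals, without both libraries numbered 3 and with the block on 2 groups were chosen after the results were seen. Of 24 main results under 454 alternatives, 407 values were classed as the same. For list tests this meant the same direction and side of the threshold. Counts of genes have neither, and were judged by how near they stayed to the main count. For the named genes 854 results gave 14664 values, of which 14017 were the same, 590 no longer passed, 18 newly passed, 38 moved and 1 reversed. The 2 filters fixed in advance removed no gene and so tested nothing, and DESeq2 has no list test. Values of these filters, 854 for each filter among the named genes, are still counted as the same in both totals, which makes the totals look more stable.

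Asking for a log2 fold change of at least 1 left 27 genes for DPAM-1 and 1326 for coronatine against DMSO, 1339 between the compounds, 310, 237 and 369 for NaCl in DMSO, DPAM-1 and coronatine, 162 for the coronatine interaction, 34, 1656 and 1589 under NaCl in the same order of compounds, and 11 shared; a stricter threshold gives fewer genes by construction. DESeq2 gave 308 for DPAM-1, 195 under NaCl and 144 shared, and the 2 groups alone gave 47 for DPAM-1 under NaCl. The cause was not tested.

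The jasmonate output list in DPAM-1 (adjusted p = 0.0446) was at 0.0518 with RLE, 0.0538 with a mean count of at least 100, 0.0578 with library totals, 0.419 with an estimated correlation, and reversed at 0.637 without DPAM-1 replicate 2. The JAZ list in DPAM-1 was at 0.279 and the abscisic acid list for NaCl in DMSO at 0.0662 with an estimated correlation. The brassinosteroid-induced list in DPAM-1, not called, pointed down at 0.471 without both libraries numbered 3. DWF1 in DPAM-1 against coronatine under NaCl reversed to 0.0673 with library totals. For these lists and genes the cause was not tested.

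Leaving out 1 library gave 76 to 173 genes for DPAM-1 against DMSO, 4166 to 5041 for coronatine, 4306 to 4763 between them, 1677 to 2241, 1179 to 1514 and 2628 to 3789 for NaCl in DMSO, DPAM-1 and coronatine, 54 to 97 and 359 to 750 for the interactions, 35 to 144, 5880 to 6298 and 5170 to 5427 under NaCl, and 36 to 116 shared. Adjusted p lay for brassinosteroid-induced genes at 0.407 to 0.946 in DPAM-1 and 7.6e-06 to 7.0e-05 in coronatine, for brassinosteroid biosynthesis at 0.349 to 0.956 and 0.394 to 0.696, for JAZ at 1.7e-05 to 0.460 and 3.2e-13 to 1.4e-11, and for jasmonate output at 4.4e-04 to 0.637 and 3.0e-18 to 7.1e-16. For the abscisic acid list it lay at 3.1e-20 to 8.9e-15 for NaCl in DMSO and at 1.6e-04 to 0.865 and 1.2e-05 to 0.399 in the interactions, and for sodium transport at 0.0773 to 0.412 in the DPAM-1 interaction.

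The replicate block gave 164, 4900 and 4941 genes without NaCl, 2446, 1700 and 3782 for NaCl, 74 and 562 for the interactions, 92, 6794 and 6001 under NaCl and 78 shared. Of 45 pairs of same-numbered libraries 3, those of DMSO and coronatine, correlated above 0.1 (median of all 0.00202), and 5 of 18 libraries resembled their own number most. Without both libraries numbered 3 there were 124 genes for DPAM-1, 4616 for coronatine and 63 and 662 for the interactions. At this depth and spread a 1.5-fold difference in the DPAM-1 interaction was recovered in 28.4% of simulated genes.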

Other observations

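The tests of overlap, of 1 library behind the jasmonate lists and of gene families were chosen after the results were seen, while leaving out each library was planned.

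Outside the fixed lists, the steepest rises after coronatine without NaCl were those of AT1G73325 (log2 6.08 ± 0.26), AT1G66100 (5.73 ± 0.22), the lectin gene JAL23 (AT2G39330) (5.72 ± 0.23), the acetyltransferase gene NATA1 (AT2G39030) (5.52 ± 0.26) and the cytochrome P450 gene CYP710A4 (AT2G28860) (5.36 ± 0.23). NATA1 stood at 3292 CPM ± 306 (SD, n = 3) against 72.0 CPM ± 5.92 (SD, n = 3) in DMSO. The steepest falls outside the lists were those of AT5G46890 (-4.52 ± 0.17) and AT3G01190 (-3.90 ± 0.21), which DPAM-1 lowered as well, to a log2 fold change of -0.88 ± 0.13 and -0.86 ± 0.17. The AT3G01190 call in DPAM-1 ended without DMSO replicate 1 or DPAM-1 replicate 1.

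Genes raised by DPAM-1 without salt may be largely genes that salt raises. To keep the libraries apart, the NaCl response in coronatine was used, which shares none with DPAM-1 against DMSO. The libraries are still not independent, since same-numbered DMSO and coronatine libraries deviated together (correlations of 0.13, 0.30 and 0.50), which adds to the overlap by an amount not measured here. Of the 114 genes raised by DPAM-1, 66 were raised there, where 16.8 are expected (57.9% against 14.7% of all genes; odds ratio 8.19, 95% confidence interval 5.54 to 12.2, Fisher's exact p = 1.3e-26). Of the 31 lowered genes 14 were lowered (3.74 expected, odds ratio 6.05, interval 2.75 to 13.1, Fisher's exact p = 4.7e-06). Genes are not independent replicates, so these p-values are too small.

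The rise of the JAZ and jasmonate output lists in DPAM-1 may rest on 1 library. The biosynthesis and catabolism list was not run without single libraries. Without DPAM-1 replicate 2 the lower adjusted p of the JAZ and output lists was 0.460, and over the alternatives the JAZ value ran from 1.7e-05 to 0.460 and the output value from 4.4e-04 to 0.637. In that library the output list lay a median of 0.65 above its group.

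A scan beyond the fixed lists covered the 128 gene families of at least 10 genes that share a product name in the reference annotation, 3346 genes in 11 comparisons. Of its 1408 results 134 passed camera with the preset correlation and 0 with an estimated one, so no family is named from it.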
